A study of Mus musculus with 3 samples.

How the data were processed

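The material was 3 libraries of 10x droplet single-cell RNA sequencing: 2 of liver cells after CCl4 injury and 1 of Col1a1-GFP-sorted cells of an Mdr2KO liver. Libraries were grouped by their titles and injury labels. The files hold raw UMI counts per gene and barcode, which the authors deposited without normalization, over 32285 genes. The submitters' processing notes name Cell Ranger 2.0.0 and the mm10 build. The annotation behind the counts and the filter that chose the barcodes are not given in the sources used here. No barcode-level annotation of cell types was used. Reporter transcripts (GFP, tdTomato) were not analysed here. Positions of named genes come from GENCODE M21 on mm10, matched by Ensembl identifier (259 of 259 looked up were found).

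Barcodes with at least 300 genes and at most 25% mitochondrial UMIs were kept: 8522 (66.2%) and 9518 (65.2%) of the CCl4 libraries and 6014 (96.4%) of the Mdr2KO library. Scrublet, as run in scanpy 1.11.5 with an expected rate of 0.08, called 69 (0.810%), 35 (0.368%) and 160 (2.66%) doublets, which were removed. The rate in CCl4 library 2 is too low for the caller to have worked there, and that in library 1 is also low. For that reason droplets with UMIs of a second lineage were set apart as mixed: at least 5 UMIs on another lineage's markers and at least 20% of the share such markers take in cells of their own class. This rule was written after the doublet calls were seen, and 2 of its exemptions were added after a first run. The CCl4 libraries were clustered together and the Mdr2KO library by itself, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Genes of the 16 gene lists, mitochondrial, ribosomal, Xist and Y-linked genes were kept out of the variable genes. Clusters were named "like" a class from 21 marker lists. The class needed a mean log2 marker score of at least 1 over the 25th percentile of clusters (pseudocount 10 CPM), at least 3 markers detected in 10% of cells, and marker levels of at least 15% of the highest cluster. This rule is the second of 2 written with the data at hand: the first misnamed clusters under the clustering alternatives. Clusters led by genes of another class, or with low UMI counts, stayed unnamed.

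Raw counts were summed per library and class. HSC-like cells of the CCl4 libraries were tested against the unweighted mean of the other classes with at least 20 cells in both libraries, by the edgeR 4.0.16 quasi-likelihood test with TMM factors, filterByExpr and the library as a block (R 4.3.3, limma 3.58.1). For the collagen score, each HSC-like cell was thinned to 1500 UMIs. Within each library the cells were parted into 3 equal ranges by their UMIs on Col1a1, Col1a2, Col3a1, Col5a1 and Col5a2, and the highest was tested against the lowest with the library as a block, leaving these 5 genes out. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Comparisons that involve the single Mdr2KO library have no test: log2 ratios of CPM are given with exact 95% Poisson intervals, and a gene differed at 2-fold or more from each library compared with at least 50 CPM on the higher side. A gene at 0 was set at a floor of 3 counts over the summed cells. A list's median ratio was placed among 10000 random lists of the same size, drawn within 50 ranks of each member's mean expression, over members of at least 1 CPM. Shares of cells carry exact binomial intervals. For shares of cells with a UMI each cell was thinned to 1500 UMIs, and shallower cells were left out. Intervals cover counting error only. Other tools were Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. The seed was 1.

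Groups, tests, marker lists, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The text names, per tested comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, changed the same way in every library and with a mean of at least 50 CPM on the higher side (20 for the collagen score). Markers, gene models and mitochondrial, ribosomal, haemoglobin and immunoglobulin genes were left out. Comparisons without a test used the size rule, ranked by the smaller ratio. Of each list up to 4 members with the smallest p or the largest ratio may also be named. Col1a1, Abcb4, Lrat and Acta2 are always given, except that Col1a1 and Abcb4 were not tested for the collagen score. The 16 lists were collagen score, contractile and cytoskeletal, matrix assembly and remodelling, hyaluronan and proteoglycan, stellate cell growth factors and cytokines, stellate cell quiescence and retinoid, TGF-beta and YAP response, chemokines and inflammatory cytokines, fibrogenic receptors, proliferation, interferon response, MHC class II, dissociation stress, endothelial angiocrine, scar-associated macrophage, and hepatocyte transcripts. The duplicated symbol Ccl21a was not matched as a marker.

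The tests were checked on simulated counts with 200 changed genes and a dispersion (spread beyond counting error) of 0.05. For HSC-like against other classes (9793 genes tested) 32 of 90 tested genes with a 2-fold change (35.6%) and 85 of 96 with a 4-fold change (88.5%) were recovered, with 5 false calls. For the collagen score (925 genes tested) 10 of 26 (38.5%) and 34 of 34 (100%) were recovered, with 2 false calls. Changed genes that the filter on low counts removed are not in these shares. The shares and false calls hold for counts of this simulated spread and are not error rates of the real data. On the real counts, 20 scores of random genes gave a median of 4 calls and a highest count of 83.

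Alternatives were DESeq2 1.42.0, RLE scaling, no TMM factors, TMM-scaled CPM, no filter on low counts, genes not used in the clustering, no library block, thinning to 1000 or 3000 UMIs or none, other ranges of the score (cells parted in 2, or the outer 2 of 6 equal parts), a contractile score, cells with the most hepatocyte UMIs left out, resolutions 0.5 and 2, doublets kept, a filter of 500 genes and 10% mitochondrial UMIs, list genes allowed in the clustering, cells with a Col1a1 UMI, mean shares per cell, 3-fold, 10 CPM, and each library left out. Added after seeing the data were the mixed droplets kept, genes at least 2 times above all kept cells, the smaller portal fibroblast-like cluster only, 20 scores of random genes with and without the Mdr2KO library, and the share of differing genes on each side as a measure of balance.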

Results

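Droplet-based single-cell RNA sequencing with unique molecular identifiers (UMIs, tags that count each captured transcript once) was done on cells of fibrotic mouse livers. In 2 libraries the injury was carbon tetrachloride (CCl4), a hepatotoxin activated in centrilobular hepatocytes, given to C57BL/6J mice in 8 intraperitoneal injections of 0.5 ml/kg at intervals of 3 days. These libraries hold liver cells of every type, enriched for non-parenchymal cells and taken 2 days after the last dose. In 1 library the injury was loss of Mdr2, the bile canalicular phospholipid transporter encoded by Abcb4, in a mouse of 3 months on an FVB background. Its non-parenchymal cells were sorted by flow cytometry for a Col1a1-GFP reporter, which marks cells that transcribe type I collagen. The numbers of the CCl4 libraries only name them. The labels do not state that they came from separate animals, so p-values measure the spread between these libraries only, estimated in part from other genes. Injury, strain, sort and depth differ together between the groups, so every comparison between them is of these libraries. With 1 Mdr2KO library it has no replicate check and no p-value.

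The CCl4 libraries held 12874 and 14588 barcodes with 32721157 and 39528374 UMIs, and the Mdr2KO library 6241 barcodes with 56198420 UMIs. Median depth per barcode was 1432 and 1721.5 UMIs against 8352 UMIs. Mitochondrial transcripts made up a median of 19.5% and 17.9% of UMIs in the CCl4 barcodes and 2.14% in the Mdr2KO barcodes. After filtering and removal of called doublets, 8453, 9483 and 5854 cells were used. Counts per gene of the CCl4 libraries differed by more than sampling noise (chi-square per degree of freedom 68.1 over 15213 genes), so the 2 files do not hold the same library. They were treated as 2 samples because the labels list them so. All libraries carried Y-linked Ddx3y (1904, 2226 and 2507 UMIs), with 3, 3 and 0 UMIs of Xist.

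Abcb4, the gene lost in the Mdr2KO mouse (ENSMUSG00000042476, chromosome 5, 8893717 to 8959231 on the forward strand of mm10), reached 96.3 and 106 CPM (UMI counts scaled by the summed UMIs) over the CCl4 libraries and 2.31 CPM over the Mdr2KO library. In hepatocyte-like cells, which normally hold this transcript, it stood at 171 and 137 CPM in the CCl4 libraries. The Mdr2KO library had 24 hepatocyte-like cells with no Abcb4 UMI, which bounds its level there at 77.6 CPM. Which part of the gene is deleted is not given in the sources used here, so the 3' counts check the label only weakly. Col1a1, the gene behind the sort, reached 278 and 149 CPM over the CCl4 libraries and 747 CPM over the Mdr2KO library. Lrat, the retinol esterifying enzyme of stellate cells, reached 52.1, 43.0 and 339.6 CPM. Acta2, the smooth muscle actin of myofibroblasts, reached 47.9, 20.9 and 107 CPM.

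Cell classes were named from fixed marker lists. Hepatic stellate cell (HSC)-like cells, named for the vitamin A-storing pericytes that are a main source of scar collagen in injured liver, were 1.16% of the cells in CCl4 library 1 (exact 95% binomial interval 0.942 to 1.41%). They were 0.854% in CCl4 library 2 (0.679 to 1.06%) and 41.3% in the sorted Mdr2KO library (40.1 to 42.6%), that is 98, 81 and 2419 cells. Hepatocyte-like cells were 54.7% and 66.5% of the CCl4 libraries. B cell-like (10.2% and 8.55%), T cell-like (5.58% and 4.27%), liver sinusoidal endothelial cell (LSEC)-like (4.98% and 3.36%) and monocyte/macrophage-like cells (4.61% and 2.94%) followed. Cholangiocyte-like cells, the bile duct epithelium, were 24.4% of the Mdr2KO library against 0.331% and 0.200% of the CCl4 libraries. Portal fibroblast-like cells, the collagen-producing cells around portal tracts, were 9.84% of the Mdr2KO library and formed no class in the CCl4 libraries. The CCl4 mesothelial-like cluster scored 4.834 for mesothelial and 2.176 for portal fibroblast markers, so portal fibroblasts within it are not excluded. An unnamed Mdr2KO cluster of 535 cells with the portal fibroblast markers Dpt and Thy1 is not in the 9.84%. Unnamed clusters held 2.18%, 1.40% and 16.2% of the cells, and 2.53%, 2.77% and 2.61% were droplets with markers of a second lineage that were set apart. Such droplets were 69 of 167 and 78 of 159 in the CCl4 HSC-like cluster and 20 of 2439 in the Mdr2KO HSC-like clusters. The sort, the enrichment and the depth can all set these shares, and intervals cover counting error only. With a filter of at least 500 genes and at most 10% mitochondrial UMIs, the mean CCl4 HSC-like share was 2.99% in place of 1.01%.

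**Figure D1:**
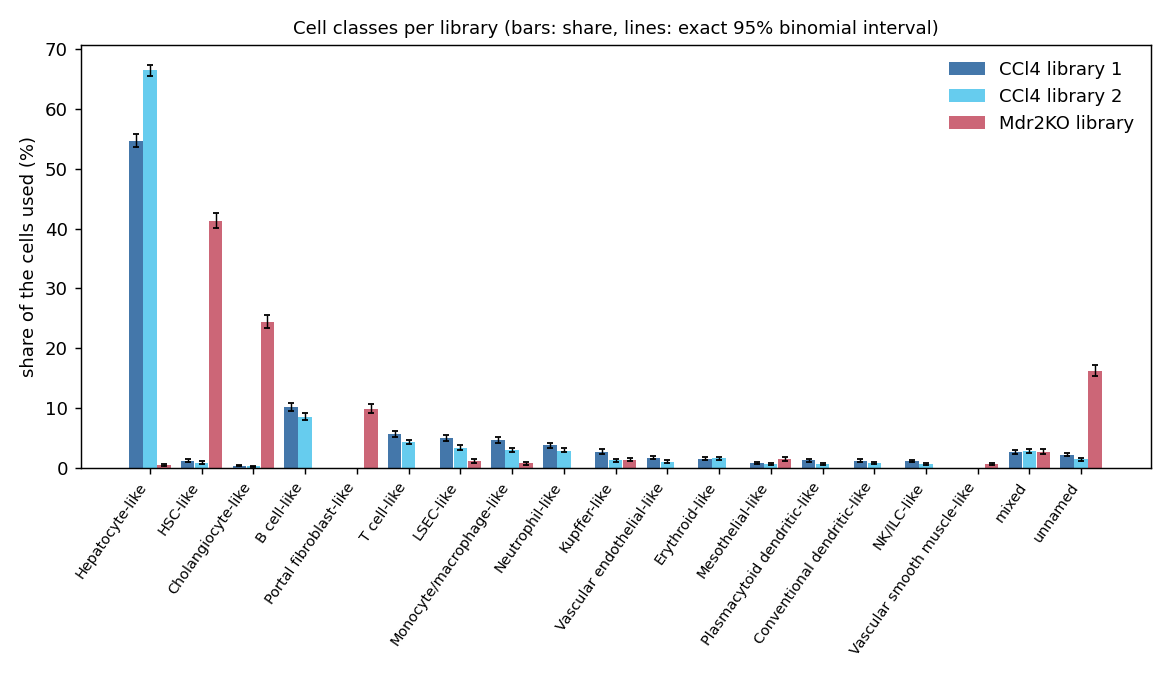
Share of the cells used (%, vertical axis) in each cell class (horizontal axis) for the 3 libraries, with exact 95% binomial intervals as lines. HSC-like cells were 1.16% and 0.854% of the CCl4 libraries and 41.3% of the Col1a1-GFP-sorted Mdr2KO library.

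Most HSC-like cells held Col1a1 transcripts in each library. With every cell thinned to 1500 UMIs, 90.8% and 80.2% of the CCl4 HSC-like cells and 64.7% of the Mdr2KO HSC-like cells had a Col1a1 UMI. Without thinning the shares were 96.9%, 95.1% and 96.4%, at median depths of 9729.5, 7575 and 7581 UMIs. Hepatocyte-like cells, which should lack the transcript, gave a background of 2.14% and 6.89% at 1500 UMIs (unthinned medians 1300.5 and 2473 UMIs, 2712 and 1678 shallower cells left out). Cholangiocyte-like cells of the sorted library gave 4.50% at 1500 UMIs and 26.0% unthinned at a median of 10719.5 UMIs. Acta2 UMIs were found in 43.9% and 27.2% of the thinned CCl4 HSC-like cells and in 5.18% of the Mdr2KO ones, with 0.261% and 0.864% in hepatocyte-like cells. For Lrat these shares were 66.3%, 63.0% and 66.1%, with 0.731% and 1.99% in hepatocyte-like cells.

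HSC-like cells of CCl4 livers were first set against the 13 other classes of the same libraries, to find the transcripts that mark them in the injured liver. They stood out by fibrillar collagens, matrix organisers and the contractile apparatus. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042 on the forward strand of mm10) reached 6684 and 4489 CPM, log2 8.59 ± 0.22 (SE) above the mean of the other classes (adjusted p = 1.36e-24). Col3a1 reached 9496 and 8364 CPM (log2 8.75 ± 0.18) and Col1a2 6733 and 5293 CPM. The next highest class for all of these was mesothelial-like cells, the liver's surface lining, with 1204 and 2840 CPM of Col1a1. Among the 10 genes with the largest rises were Ltbp2, which binds microfibrils (314 and 316 CPM), Postn, a matrix protein of scars (823 and 679 CPM), Adamts2, a procollagen peptidase (395 and 420 CPM), and Tcf21, a mesenchymal transcription factor (349.6 and 322 CPM). With Col1a2, the other genes among the 10 were Islr, Fbln5, Ednra, the endothelin receptor, Tbx20 and Ccbe1. Tbx20 and Ccbe1 were not called by DESeq2 (adjusted p = 0.124 and 0.297). The largest falls were of leukocyte and hepatocyte genes. They were Hcst, a signalling adaptor of lymphocytes (log2 -3.13 ± 0.56, adjusted p = 2.49e-05), Iqgap2 (-2.83 ± 0.25), the acute-phase gene Saa2 (-2.65 ± 0.22), the integrin Itga4 (-2.64), Gmfg, Arhgap45, Gchfr, Serpinf2, Rac2 and Srgn. Abcb4 stood at 5.70 and 7.32 CPM (log2 -2.59 ± 0.32, adjusted p = 5.03e-08). The fall of Hcst was not called with mixed droplets kept, with called doublets kept or at clustering resolution 2. Of 11304 genes tested, 3254 were higher and 1245 lower in HSC-like cells at an adjusted p below 0.05 (edgeR quasi-likelihood test, n = 2 libraries with the library as a block). The classes were clustered from these same counts, so the p-values are not those of an independent test. All classes also shared the same estimate of each gene's spread. Among the 9631 genes not used in the clustering, 2803 were higher and 882 lower. All genes named for this comparison moved the same way in both libraries. Genes near 0 in other classes have fitted log2 values that depend on the prior count, so their CPM is the safer measure.

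Grouped by the lists fixed beforehand, all 26 tested members of matrix assembly and remodelling were higher in HSC-like cells (camera adjusted p = 2.09e-30, adjusted p = 0.0126 with an estimated correlation). Dcn, a small proteoglycan that binds collagen fibrils, reached 5437 and 6521 CPM (log2 7.87 ± 0.16), and Sparc, Bgn and Col14a1 rose with it. All 5 collagen score genes rose (6.35e-10; 0.0167 with an estimated correlation). All 10 contractile and cytoskeletal genes rose (3.55e-12; 0.0198). Acta2 stood at 1099 and 490.3 CPM (log2 7.37 ± 0.24, adjusted p = 1.44e-21) and Tagln, an actin-binding protein, at 1911 and 1505 CPM. All 16 tested growth factors and cytokines of stellate cells rose (5.14e-16; 0.0126). Cxcl12, the chemokine that retains leukocytes and progenitors, reached 1540 and 1919 CPM, Gdf2, which encodes the endothelial ligand BMP9, 413 and 404 CPM, and Bmp5 231 and 258 CPM. Of 15 fibrogenic receptors 14 rose (6.96e-13; 0.0126), among them Pdgfrb, the platelet-derived growth factor receptor (408 and 552 CPM), and the integrin Itga8. Pdgfrb also served as a naming marker of HSC-like cells, so its rise is not independent evidence. Of 11 TGF-beta and YAP response genes 9 rose (4.62e-06; 0.00448), with Tgfbi at 800 and 1020 CPM. Of 14 quiescence and retinoid genes 11 rose and 1 fell (6.12e-13; 0.0126). Lrat stood at 884 and 913 CPM and Reln at 645 and 814 CPM. Of the 15 genes on that list 7 also served as naming markers, so its direction is not independent evidence.

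Cell cycle genes were also higher: of 12 proliferation genes 11 rose (camera adjusted p = 0.000419), a list call lost with an adjusted p = 0.0991 with an estimated correlation. Top2a, the topoisomerase of dividing cells, stood at 197 and 130 CPM (log2 2.26 ± 0.24, adjusted p = 1.19e-09). Of 10 interferon response genes 6 rose, 7 when adjusted over the list alone, and the list did not pass (adjusted p = 0.0504, and 0.307 with an estimated correlation). Isg15 (2.03 ± 0.19) and Ifit3 (3.56 ± 0.39) led it. Of 10 endothelial angiocrine genes 8 rose over the class mean, yet the list did not pass (0.0504, and 0.331 with an estimated correlation). LSEC-like cells had the highest level of Bmp2, 1452 CPM against 91.2 and 51.2 CPM in HSC-like cells. Of 11 scar-associated macrophage genes 5 rose and 1 fell (0.528). Trem2 (81.7 and 99.5 CPM, against 968 CPM in monocyte/macrophage-like cells) and Gpnmb lost their calls under the stricter cell filter (adjusted p = 0.113 and 0.183). Of 14 chemokine and cytokine genes 5 rose and 2 fell (0.636), and of 15 dissociation stress genes 5 rose and 3 fell (0.528), with a median of 0.11 and a mean of 0.27 although camera ranked the list downward. Among 5 hyaluronan genes only Vcan rose, with a list median of -0.00, a mean of 0.98 and a downward rank (0.941). None of 5 MHC class II genes changed (0.528; 0 genes at an unadjusted p below 0.05). All 10 hepatocyte transcripts fell (3.15e-12; 0.0452). Of these 9 were naming markers of hepatocyte-like cells, and they were found in every class: Ttr stood at 542 and 449 CPM in HSC-like cells against a mean of 11491 CPM in hepatocyte-like cells. Apart from the interferon list, counts adjusted over the list alone equalled those given.

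**Figure D2:**
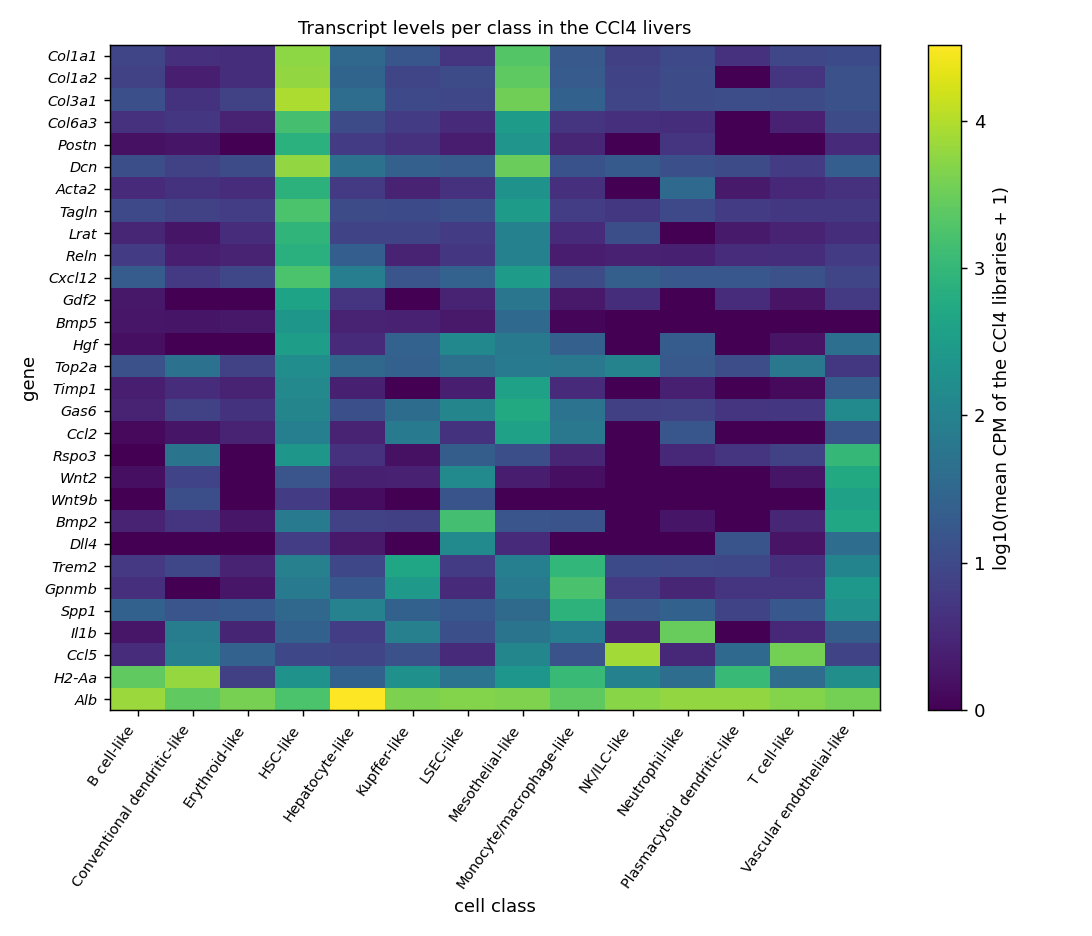
Transcript level (colour, log10 of the mean CPM of the 2 CCl4 libraries plus 1) of 30 genes (vertical axis) in 14 cell classes (horizontal axis) of the CCl4 livers. HSC-like cells had the highest levels of Col1a1, Cxcl12 and Gdf2, and the neighbouring levels in mesothelial-like cells were lower, such as 1204 and 2840 CPM of Col1a1 in the 2 libraries.

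The same libraries show which cell class had the highest CPM of each listed ligand, receptor and matrix transcript. CPM is a level within a class, so the first class need not hold most of the UMIs. Of 202 listed genes, 176 reached 50 CPM in some class, and for 66 of these HSC-like cells ranked first in both CCl4 libraries. Mesothelial-like cells ranked first for 17, vascular endothelial-like cells for 13, hepatocyte-like cells for 12, LSEC-like and monocyte/macrophage-like cells for 8 each, Kupffer-like cells for 6 and neutrophil-like and conventional dendritic-like cells for 5 each. For 33 genes the first class differed between the libraries. HSC-like cells led for 5 of 5 collagen score genes, 17 of 26 matrix genes, 7 of 10 contractile genes, 11 of 13 quiescence genes, 9 of 15 growth factors, 7 of 15 receptors and 5 of 8 proliferation genes. They led for 2 of 11 TGF-beta and YAP response genes, 2 of 8 interferon genes and 1 of 10 scar-associated macrophage genes. They led for 0 of the hyaluronan, chemokine, MHC class II, dissociation stress, angiocrine and hepatocyte genes.

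The following examples of sources were chosen after their values were seen. Hgf, the hepatocyte mitogen, was highest in HSC-like cells (305 and 366 CPM), and so was the guidance factor Ntn1 (212 and 202 CPM). Vascular endothelial-like cells had the highest levels of the Wnt ligands Wnt2 (644 and 459 CPM) and Wnt9b (414 and 344 CPM). The same held for the Wnt amplifier Rspo3 (945 and 1081 CPM, against 213 and 283 in HSC-like cells). The cluster of that class with these leading genes scored higher for LSEC markers (4.989) than for vascular endothelial markers (3.39). Its other cluster scored higher for Kupffer markers (4.931) than for vascular endothelial markers (3.763). The split between vascular endothelial-like and LSEC-like sources is therefore not firm. LSEC-like cells had the highest levels of Bmp2 (1639 and 1264 CPM), the iron-regulating ligand of hepatocytes, and of Tgfb1 (257 and 279 CPM). Timp1, an inhibitor of matrix proteases, peaked in mesothelial-like cells (462 and 313 CPM) rather than in HSC-like cells (146 and 122 CPM). Trem2 (911 and 1026 CPM) and Gpnmb (1616 and 1724 CPM) peaked in monocyte/macrophage-like cells. Il1b peaked in neutrophil-like cells (2737 and 3011 CPM), Ccl5 in NK/ILC-like cells (7484 and 7969 CPM) and Igf1 in Kupffer-like cells (595 and 459 CPM). These are levels without a test, and their order covers the 14 classes with at least 20 cells in each library, which leaves out cholangiocyte-like cells (28 and 19 cells).

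HSC-like cells of the 2 injuries were then compared. The CCl4 cells held more transcripts of the collagen score genes, of Acta2 and of cell cycle genes, and the Mdr2KO cells more Cxcl12, Cxcl14 and dissociation stress genes. Col1a1 stood at 883 CPM in the Mdr2KO library (exact 95% Poisson interval 870.2 to 897) against 6684 (6528 to 6842) and 4489 CPM (4332 to 4651) in the CCl4 libraries, a log2 ratio of -2.66. Acta2 stood at 74.5 against 1099 and 490.3 CPM (-3.41), Postn at 53.6 against 823 and 679 CPM (-3.81), Col6a3 at 342 against 1694 and 1317 CPM (-2.14) and Ltbp2 at 7.07 against 314 and 316 CPM (-5.48). Abcb4 stood at 1.64 CPM (1.11 to 2.32) against 5.70 (2.09 to 12.4) and 7.32 CPM (2.38 to 17.1), under the 50 CPM of the rule for differing genes. Lrat hardly differed, at 853 against 884 and 913 CPM (-0.07, and 0.49 under TMM scaling). Cxcl12 was higher in the Mdr2KO library, at 4401 against 1540 and 1919 CPM (1.35). Cxcl14, a chemokine of fibroblasts, stood at 1654 against 97.9 and 79.0 CPM (4.23), Ccn1, a YAP target, at 1111 against 86.5 and 310.3 CPM (2.49), and Hspa1a, a heat shock protein, at 166 against 9.50 and 8.78 CPM (4.19). Intervals cover counting error only.

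By the rule of a 2-fold difference from each CCl4 library at 50 CPM or more, 975 genes differed, 303 higher in the Mdr2KO and 672 in the CCl4 libraries. The share higher in Mdr2KO was 31.1%. TMM-scaled CPM moves every log2 ratio by 0.57 towards Mdr2KO and turns this balance, to 1029 against 263 of 1292 genes (79.6%), and 566 of the 975 genes kept their call. Among the largest ratios on the Mdr2KO side were also Mgp, an inhibitor of calcification (1065 against 61.8 and 48.3 CPM), Egfem1, Tmtc2, Cd200, Ctla2a, Alad, Clec14a and Cxcl1. Mgp and Cxcl1 were lower in HSC-like cells than over all kept cells of that library. The 10 largest ratios on the CCl4 side held the cell cycle genes Hmmr, Prc1, Top2a and Racgap1. Top2a stood at 0.581 against 197 and 130 CPM and Prc1, a spindle midzone protein, at 0.369 against 131 and 101 CPM. Hmmr had no UMI in the Mdr2KO cells against 60.8 and 60.0 CPM, at least 379-fold higher in the CCl4 libraries over a floor of 3 counts. The macrophage genes Cybb, Mpeg1, Laptm5 and Trem2 and the hepatocyte genes Fabp1 and Uox were also on that side. Laptm5, Fabp1 and Uox were lower in the HSC-like cells than over all kept cells in both CCl4 libraries, and Cybb, Mpeg1 and Trem2 in library 1 but not in library 2.

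**Figure D3:**
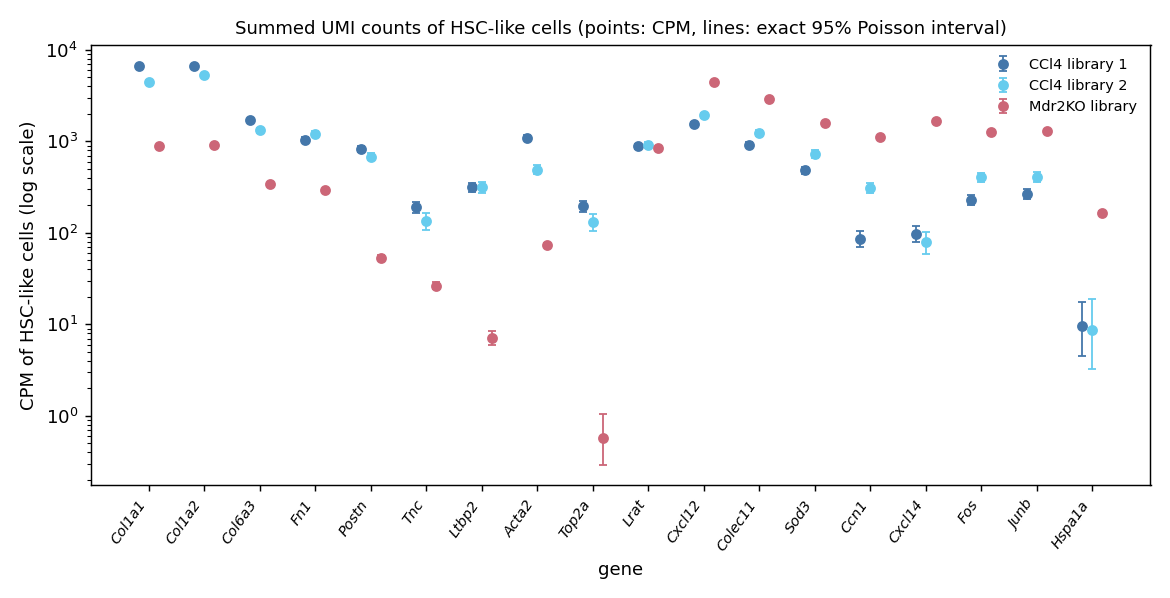
CPM of summed UMI counts of HSC-like cells (vertical axis, log scale) for 18 genes (horizontal axis) in the 3 libraries, with exact 95% Poisson intervals as lines, which cover counting error only. Col1a1 stood at 6684 and 4489 CPM in the CCl4 libraries and 883 CPM in the Mdr2KO library, and Cxcl12 at 1540 and 1919 against 4401 CPM.

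By list, the median log2 ratio of the collagen score genes was -2.54, at the 0.205 percentile of 10000 random lists matched on expression, and all 5 were lower in Mdr2KO (TMM median -1.98). Matrix genes had a median of -0.93 (percentile 0, TMM -0.37), with 11 of 26 lower, such as Tnc and Fn1, and 4 higher, but 5 lower and 4 higher under TMM. Proliferation genes had a median of -5.43 (percentile 0), with 8 of 12 lower. Fibrogenic receptors had a median of -0.74 (0.635, TMM -0.17), with only Ednrb past the rule, and 0 lower and 1 higher under TMM. Dissociation stress genes, which cell isolation can induce, had a median of 1.01 (99.99; TMM 1.58) with 6 of 16 higher in Mdr2KO (9 under TMM), such as Fos at 1280 against 228 and 404 CPM and Junb at 1298 against 266 and 408 CPM. Hepatocyte transcripts (-5.87, percentile 0, 9 of 10 lower, TMM 8), MHC class II genes (-4.52, 0.09, 4 of 5) and scar-associated macrophage genes (-1.57, 0.01, 6 of 10 lower and 1 higher, TMM 4 and 2) had lower medians in the Mdr2KO cells. Cd74 and H2-Aa, MHC class II genes, stood at 394 and 799 CPM and at 151 and 243 CPM in the CCl4 HSC-like cells, below the 1491 and 953 CPM and 510.3 and 301 CPM over all kept cells. Angiocrine genes had a median of -2.93 (0.12), but only 1 of 10 was past the rule, and 0 under TMM. Quiescence genes had a median of 0.31 (80.7; TMM 0.88), with Colec11 (2880 against 924 and 1231 CPM), Sod3 and 1 other of 15 higher (5 under TMM). The median changed sign with the scaling in 4 lists. Contractile genes moved from -0.55 (1.51), with 1 of 10 lower, to 0.02 under TMM, with 1 higher and 1 lower. TGF-beta and YAP genes moved from -0.34 (29.3), with 3 of 14 either way, to 0.23, with 5 higher and 2 lower. Chemokines moved from -0.08 (96.2), with 3 of 15 higher and 1 lower, to 0.49, with 3 higher and 0 lower. Growth factors moved from -0.00 (56.0), with 1 of 17 higher and 3 lower, to 0.56, with 2 higher and 1 lower. Interferon (-0.68, 14.1) and hyaluronan genes (0.18, 92.3) had 0 members past the rule. The cells lie in CCl4 cluster 15 and Mdr2KO clusters 0, 2, 6, 8 and 9, clustered separately.

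Within the HSC-like cells of each library, those rich in collagen UMIs were set against those poor in them, to find genes that go with collagen expression in both injuries. S100a6 (ENSMUSG00000001025, chromosome 3, 90612882 to 90624181, forward strand), a calcium-binding protein, was the only gene that rose with the score. Its log2 difference was 2.37 ± 0.32 (SE; edgeR adjusted p = 0.0114, higher in 3 of 3 libraries). It went from 294 to 1959 CPM and from 49.6 to 1178 CPM in the CCl4 libraries and from 203 to 730.2 CPM in the Mdr2KO library. Of 935 genes tested 1 rose and 0 fell, with 95 genes at an unadjusted p below 0.05 (edgeR with the library as a block, n = 3). DESeq2 called 4 up and 6 down, RLE scaling 8 up and 6 down, and library sizes without TMM factors 2 up and 4 down. S100a6 was not called without CCl4 library 1 (adjusted p = 0.0582), without CCl4 library 2 (0.151), without a block (0.975), at 1000 UMIs per cell (0.0676), under the stricter cell filter (0.0614) or with mixed droplets kept (0.25). Of 20 scores made from 5 random genes of like abundance, 15 gave at least 1 called gene, with a median of 4 and a highest count of 83. The score ranges are not cell types: 36, 31 and 2220 cells lay within 5 UMIs of a limit, and the medians of the low and high range were 12.5 and 56.5, 8 and 52, and 3 and 10 collagen UMIs.

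Among the lists fixed beforehand, matrix genes tended upward and quiescence genes downward with the collagen score. Adjusted over the list alone, 8 of 22 matrix genes rose and 1 fell, against 0 over all genes (camera adjusted p = 1.2e-07; adjusted p = 0.354 with an estimated correlation). Col6a3, a chain of the pericellular type VI collagen, had a log2 difference of 1.62 ± 0.36, Timp1 1.26 and Sparc 0.64, while Dcn had -0.57. Of 11 quiescence genes 5 fell and 0 rose when adjusted over the list alone, against 0 over all genes (1.2e-07; 0.482 with an estimated correlation). They included Ecm1 (-1.33 ± 0.26, adjusted p over all genes 0.103), Rgs5, a regulator of G protein signalling in pericytes (-1.56), and the collectins Colec10 (-1.69) and Colec11 (-1.46). Over their lists alone, Igf1 rose (1.35) and Angptl6 fell (-1.89) of 9 growth factors (0.0639), and Ltbp2 rose (3.79) and Tgfbi fell (-0.80) of 4 TGF-beta and YAP genes (0.556; median -0.16, mean 0.67). No gene of the contractile (10 tested, 0.296), receptor (7, 0.916), dissociation stress (9, 0.228), scar-associated macrophage (3, 0.556) and hepatocyte lists (7, 0.556) passed either way, nor did the 1 chemokine, 2 proliferation, 2 interferon and 2 MHC class II genes tested. Acta2 had 1.07 (adjusted p = 0.418) and Lrat -0.47 (0.513). The hyaluronan and angiocrine lists had 0 tested genes, and the collagen score genes were left out. Receptors had a median of 0.10 and a mean of -0.02.

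The fit on the 2 CCl4 libraries alone called 62 genes up and 66 down of 722, and it was decided to describe them only after this count was seen. With so few sums the test took each gene's spread almost wholly from all the genes tested. Its p-values and calls therefore do not measure a gene's own spread between the 2 libraries. Col6a3 (log2 2.60 ± 0.23, adjusted p = 3.86e-25), S100a6 (3.08), Mmp2, a gelatinase (2.80), Serpine2, Cpxm1, Alcam, Adamtsl2, Loxl1 and Islr were higher in collagen-high cells. Ltbp2 went from 0 UMIs to 588 and 563 CPM, with only 32 and 27 thinned cells in each range. Colec11 (-2.41), Angptl6 (-4.06), Colec10 (-2.23), Lama1, Tmem56, Adamts1, Tnfrsf11b, Clca3a1, Top2a (-2.41) and the macrophage genes C1qb (-2.58) and Lyz2 (-2.40) were lower. The matrix list (9 of 22 rose, 1 fell; 11 and 1 over the list alone) and the quiescence list (1 rose, 7 fell of 10) passed at adjusted p = 0.000115 and 5.8e-05, but not with an estimated correlation (adjusted p = 0.815 for both). Of 20 random scores 1 gave as many calls on these libraries, with a median of 19.5. In the Mdr2KO library 98 of the 128 genes (76.6%) had the same sign, against 65.1% of all tested genes. Their median size was 1.46 in the CCl4 libraries, which selected them, and their median signed value 0.14 in Mdr2KO. These measures are unlike, and the Mdr2KO score ranges lay closer together. Their medians were 3 and 10 collagen UMIs, against 12.5 and 56.5 and 8 and 52 in the CCl4 libraries. A difference between the injuries was not tested.

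**Figure D4:**
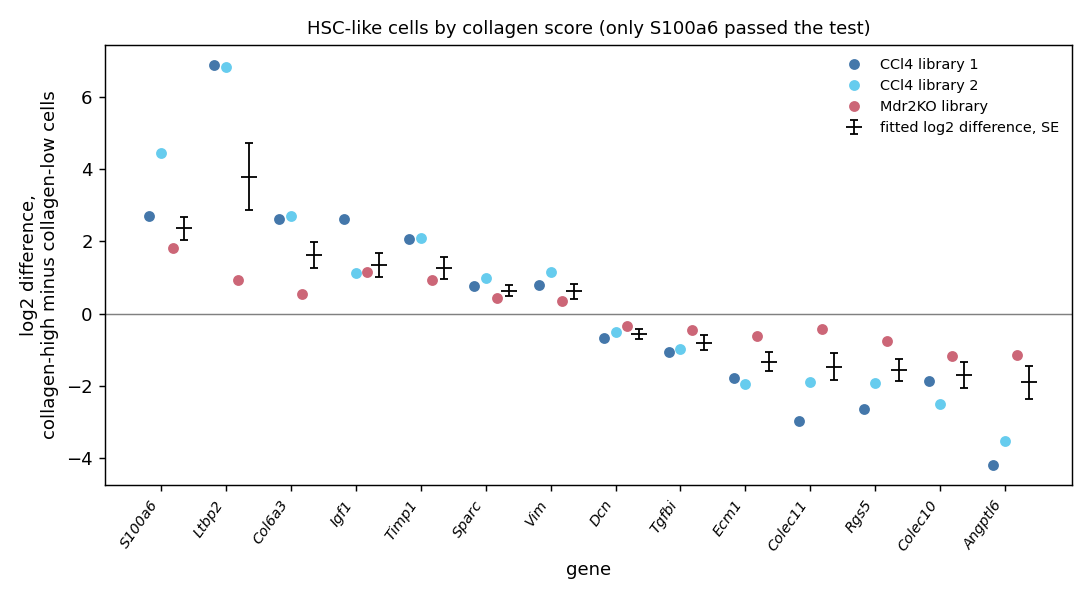
Log2 difference of CPM between collagen-high and collagen-low HSC-like cells (vertical axis) for 14 genes (horizontal axis), with coloured points for each library and the fitted value ± SE in black. S100a6 was the only gene that passed, at 2.37 ± 0.32.

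Finally, HSC-like cells were compared with portal fibroblast-like cells of the Mdr2KO library (2419 and 576 cells, 1 library, no test). An unnamed cluster of 535 cells, left out here, held as much Col1a1 (2293 CPM) as portal fibroblast-like cells, and vascular smooth muscle-like cells held 501 CPM. That unnamed cluster also held Dpt (565 CPM), Thy1 (99.1 CPM) and Ptn (1073.5 CPM), against 365, 98.7 and 378 CPM in the larger portal fibroblast-like cluster. Its Gli1 was lower (0.642 against 3.00 CPM) and its Spp1 higher (18832 against 2496 CPM). The contrast below and the 9.84% share of portal fibroblast-like cells therefore depend on leaving it out. Portal fibroblast-like cells held more collagen score transcripts, elastin and Sfrp1, and HSC-like cells more quiescence and retinoid transcripts, Angptl6 and Gdf2. Col1a1 stood at 883 CPM in HSC-like and 2243 CPM (2200.0 to 2286) in portal fibroblast-like cells, a log2 ratio of -1.34. Eln, elastin, stood at 134 against 611 CPM (-2.19), Acta2 at 74.5 against 292 CPM (-1.97), Vegfd, a lymphangiogenic factor, at 10.6 against 219 CPM (-4.37), and Mmp2 at 203 against 657 CPM. Sfrp1, a Wnt inhibitor, stood at 4.91 against 419 CPM (-6.42), Fxyd6 at 6.07 against 569 CPM (-6.55) and Ptn, a heparin-binding growth factor, at 4.96 against 368 CPM. Wif1, another Wnt inhibitor, had 1 UMI in HSC-like cells (interval up to 0.294 CPM) against 51.9 CPM (45.6 to 58.9) in portal fibroblast-like cells. Nearly all of it came from the smaller of their 2 clusters (94 cells, 364 CPM), with 1 UMI in the larger (482 cells). Acta2 also differed between these clusters, at 989.7 and 177 CPM. Abcb4 stood at 1.64 against 1.93 CPM (0.883 to 3.66), a difference not detectable at this depth. On the HSC-like side, Lrat stood at 853 against 186 CPM, Rgs5 at 1641 against 36.0 CPM, Colec10 at 144 against 2.57 CPM (5.81), Angptl6 at 259 against 6.01 CPM (5.43) and Gdf2 at 411 against 26.0 CPM (3.99). Tgfbi (2969 against 485 CPM), Col14a1 (843 against 218 CPM) and the monocyte chemoattractant Ccl2 (202 against 35.6 CPM) were also higher there.

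By the 2-fold rule 340 genes differed, 190 higher in HSC-like (55.9%) and 150 in portal fibroblast-like cells. The balance turned with 3-fold (47.6% of 185) and with 10 CPM (46.9% of 796). Further genes on the HSC-like side were Egfem1, Tmem56, Fcna, Ntm, Apold1, Rgs4 and Ank3, and on the other side Fbn2, Saa3, Col6a5, Col6a6, Serpinf1 and Cpxm2. Quiescence genes had a median of 1.57 (percentile 100, 10 of 14 higher in HSC-like), which their use as markers favours. Chemokines had 1.06 (percentile 100, 3 higher and 1 lower of 11), dissociation stress genes 0.71 (percentile 100, 3 of 16), growth factors 0.36 (99.86, 6 higher and 4 lower of 17), receptors 0.25 (97.9, 3 of 14), and interferon genes 0.77 (99.99, 0 of 9). Collagen score genes had -1.04 (0.1, 3 of 5 lower), matrix genes -0.50 (0, 6 lower and 2 higher of 26) and scar-associated macrophage genes -1.25 (0.02, 3 of 8 lower), among them Spp1. Contractile genes had -0.03 (36.9, 1 of 10 lower), hyaluronan genes -0.11 (10.5, 0 of 6), TGF-beta and YAP genes 0.06 (52.0, 2 of 14 each way), proliferation genes -0.12 (43.3, 0 of 8), MHC class II genes -1.18 (0.29, 0 of 4), angiocrine genes 0.43 (93.9, 0 of 6) and hepatocyte transcripts 0.06 (59.95, 1 of 9 lower). The unnamed cluster of 535 cells scored 2.608 for its best class and 1.524 for HSC, but it stayed unnamed because genes of another class led it. The larger portal fibroblast-like cluster scored lower and was named by a narrow margin (score 2.329 against 2.273 for HSC). In the smaller cluster alone, a choice made after seeing the data, Saa3 had 0 CPM and Spp1 177 CPM. With called doublets kept, Saa3 (log2 2.93), Fbn2 (0.14) and Spp1 (1.91) were higher in HSC-like cells. In that setting the HSC-like share rose as well, so the classes did not hold the same cells.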

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

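The tests of depth, sort, RNA from other cells, chance pairs of cells and other splits of the sums were chosen only after the results were seen. In the score comparison, 4 of the genes named for the CCl4 libraries fell with the collagen score in both of them and had the opposite sign in the Mdr2KO library. Their Mdr2KO log2 differences were 0.0069 for Lama1, 0.129 for C1qb, 0.223 for Top2a and 0.132 for Lyz2. From collagen-low to collagen-high Mdr2KO cells, Lama1 went from 28.2 to 28.4 CPM and Lyz2 from 22.4 to 25.1 CPM. C1qb went from 4.15 to 5.01 CPM and Top2a from 0 to 0.835 CPM. These levels hardly changed or lay near the floor, so their signs show no rise in that library. A difference between the injuries was not tested. S100a6 itself was the 1 call of the blocked fit. The 10 splits of the 6 sums into equal groups are too few for a share under 0.05: without the block the real split gave 0 calls and the highest other split 1, so 10 of 10 gave as many. Of the 4 splits that part every library's pair, with the block, the real one gave 1 call and the others 0. Of 20 random scores 15 gave at least as many calls as the collagen score.

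Signals outside the main comparisons were found in the sorted library. Cholangiocyte-like cells made up 24.4% of it although the sort was for Col1a1, with Col1a1 at 31.0 CPM in them. The largest unnamed cluster (535 cells) held Col1a1 at 2293 CPM, with Mgp at 17615 CPM and Spp1 at 18832 CPM. In the LSEC-like cluster 53 of 117 droplets carried HSC markers.

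Higher collagen transcripts in the CCl4 than in the Mdr2KO HSC-like cells, with a median log2 ratio of -2.54 for the collagen score genes, were weighed first. A gap in depth does not account for it: HSC-like cells of CCl4 library 2 had a median of 7575 UMIs against 7581 UMIs in the Mdr2KO library, and against that library alone the median ratio was -2.35. RNA from other cells does not either, since Col1a1 over all kept CCl4 cells reached at most 4.99% of its HSC-like level. Selection by the sort for Col1a1 would raise the Mdr2KO level, opposite to the pattern, but other effects of sorting remain open: requiring a Col1a1 UMI left the median at -2.55 and removed few cells, 96.9%, 95.1% and 96.4% having one already. The handling of cells in the sort, the kind of damage, the strain or the stage of fibrosis may each account for it and cannot be told apart, because they differ together between the groups.

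In the HSC-like cluster of the CCl4 libraries, 79.1% and 75.6% of the droplets that carried LSEC, Kupffer, T cell or B cell markers carried LSEC markers. Chance pairs of cells would give about 21.2% and 19.3%, the LSEC-like share among cells of those 4 classes, which lies outside the exact intervals (67.4 to 88.1% and 64.6 to 84.7%). That reading assumes that each lineage's markers are detected equally well in a pair. Single cells with both programmes and cells that stayed attached to each other both remain candidate explanations. Against attached cells, HSC marker UMIs were not diluted as that reading requires (1.05 and 0.943 times the share of the other HSC-like cells), and median depth was close (9821 against 9729.5 and 8156.5 against 7575 UMIs), but library 2 fell just short of the bound set beforehand for excluding it.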

How the results depend on the processing

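Keeping mixed droplets, genes above all kept cells and the smaller portal fibroblast-like cluster were tried only after the results were seen. Counts of the CCl4 HSC-like class rest on 98 and 81 cells (1052580 and 683203 UMIs), and those of the Mdr2KO class on 2419 cells (18945404 UMIs). No paired analysis was possible because the groups share only a replicate number given in accession order and the Mdr2KO group has 1 library. The comparison of HSC-like with other classes gave between 3685 and 5176 calls over all alternatives, within 1.5 times of 4499, and at least 3349 of the 4499 genes were called with the same sign (the stricter filter). Its single-library medians were 1.25 and 1.25 (higher) and -0.77 to -0.74 (lower), and 7 of 670 values of named genes lost their call. Sources led by HSC-like cells ranged from 60 to 77 genes against 66, and from 72 to 73 with a library left out.

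The CCl4 HSC-like share of 1.01% became 1.55% at resolution 0.5, 1.496% at resolution 2, 2.99% with the stricter filter and 1.83% with mixed droplets kept, and 0.854% to 1.16% with a library left out. The Mdr2KO share of 41.3% became 43.9% at resolution 2 and 48.3% with doublets kept.

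The collagen score count of 1 was the least stable. It became 10 with DESeq2, 14 with RLE, 6 without TMM factors, 38 without the filter, 0 without the block (28 unadjusted), 0 at 1000 UMIs (52 unadjusted), 69 at 3000 UMIs and 10 without thinning. It was 39 with the cells parted in 2, 42 with the contractile score, 3 without cells rich in hepatocyte UMIs, 8 and 14 at resolutions 0.5 and 2, 45 with doublets kept, 0 with the stricter filter (84 unadjusted), 9 with list genes in the clustering and 128 with the 2 CCl4 libraries only. With a library left out it ranged from 0 to 128. Col6a3 turned to -0.080 with the contractile score (adjusted p = 0.916, against a range of 3.86e-25 to 1.00 over its alternatives). The cause of these shifts was not tested.

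For the 2 injuries, 975 genes became 376 at 3-fold, 2749 at 10 CPM and 256 above all kept cells, and 1190 to 1241 with a library left out. The share higher in Mdr2KO, 31.1%, became 79.6% under TMM scaling, which adds 0.57 to every log2 ratio. It became 21.0% at 3-fold, 17.6% at 10 CPM, 14.5% above all kept cells and 25.8% with mixed droplets kept, and 33.7% to 34.2% with a library left out. The 14.5% says nothing of the balance: HSC-like cells are 41.3% of the Mdr2KO library, so few of its genes can stand 2 times above all kept cells. Of 57 named genes only Lrat (-0.07) changed sign, to 0.21 at resolution 0.5, 0.017 with the stricter filter and 0.49 under TMM scaling. Against portal fibroblast-like cells, 340 genes became 185 at 3-fold, 796 at 10 CPM and 518 with the smaller cluster only, and the HSC-like side fell from 55.9% to 47.6% at 3-fold and 46.9% at 10 CPM. With doublets kept Saa3 (2.93), Fbn2 (0.14) and Spp1 (1.91) turned towards HSC-like cells. With the smaller cluster only Spp1 (0.53) and Fabp5 (0.61) did. Keeping doublets also raised the HSC-like share and left 225 of the 340 genes with their call, so the classes held other cells. These turns can therefore not be put down to the doublets themselves. The cause was not tested. Of the other named genes only Abcb4 changed sign, between -1.09 and 0.27 with too few UMIs to tell the classes apart.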

Other observations

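No test in this part was chosen after its result was seen, but the patterns tested were noticed in the same data. Beyond the classes compared above, the CCl4 livers held an unnamed cluster led by the plasma cell genes Jchain and Igha. In the sorted Mdr2KO library, vascular smooth muscle-like cells had the highest Acta2 level, 8696 CPM, against 74.5 CPM in HSC-like and 292 CPM in portal fibroblast-like cells. An unnamed cluster of 300 cells at a median of 14602 UMIs combined Epcam, an epithelial adhesion molecule (311 CPM), with Spp1 (15023 CPM) and Alb (3718 CPM). In the CCl4 libraries 24 and 80 droplets of hepatocyte-like clusters carried HSC markers, and 17 of 165 and 22 of 123 droplets of vascular endothelial-like clusters carried Kupffer cell markers.

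The hepatocyte-like cells of the 2 CCl4 libraries differed although the labels give both the same treatment. By the 2-fold rule 71 genes differed, 39 higher in library 1, among them the fatty acid hydroxylases Cyp4a14 and Cyp4a10, the phosphatidate phosphatase Lpin1 and the glucocorticoid target Fkbp5. Another 32 were higher in library 2, among them Foxq1 and the mesenchymal genes Dcn, Col3a1, Col1a1 and Sparc. The leukocyte genes Lyz2, Cd74 and Tyrobp were also among them, at 26.4, 32.4 and 21.6 CPM in library 1. In library 2 these leukocyte genes stood at 104, 117 and 75.4 CPM. Whether transcripts of other cells in these droplets account for the genes higher in library 2 was not tested. Leaving out shallow cells and cells rich in mitochondrial UMIs did not remove the difference between the libraries. Of 66 genes 98.5% kept a 1.5-fold difference in the same direction among cells with at least 500 genes and at most 10% mitochondrial UMIs. These cells are part of those that picked the genes, and RNA leaked from damaged cells can lie in droplets that pass the filter. Leaky or damaged cells are therefore not excluded as a cause. A different time of day at collection may contribute and is not decided: clock output genes (Dbp, Per1, Per2, Per3, Tef, Nr1d1, Nr1d2 and Ciart) had a median log2 ratio of library 1 to library 2 of 0.93, while Arntl, Npas2 and Clock had -0.34, short of the 0.58 set beforehand for both.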
